A study of Mus musculus with 2 samples.

How the data were processed

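H3K36me3, the trimethylated lysine of histone H3 that marks the bodies of transcribed genes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in liver of mouse embryos at embryonic day 11.5. Per the labels, the 2 samples are biological replicates of 1 group, each made from livers of embryos of both sexes pooled together, with 3 technical replicates listed for each and fragments selected between 300 and 500 bp. The 2 replicates come from separately collected pools. Replicate 1 was made from 109 embryos, and the number of embryos in replicate 2 is not given in the sources used here.

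The deposited values are peak lists on the mouse build mm10, in narrowPeak format. Per the file headers and the text notes deposited with the samples, 1 list was called for each replicate from its own merged reads, 1 list from the reads of both replicates pooled, and 1 list of replicated peaks was derived from the pooled list and the replicate lists. Replicate 1 was called against 2 further alignments and replicate 2 against 1 of these 2, which those notes use as controls. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. Every replicated peak has the coordinates of a pooled peak. Each peak carries the authors' signal value, treated here as a score whose scaling is not given, and the authors' p-value and q-value against the control as −log10 p and −log10 q. The lowest −log10 p was 2.02 in replicate 1 and 2.00 in replicate 2. Signal values, p and q were used to describe, rank and filter peaks within a list. The closing section also sets p of the 2 replicates side by side at equal signal values, and nothing is drawn from that comparison because the scaling may differ between lists. Read counts were not used here, so the sequencing depth of each replicate is unknown and no interval that needs a depth is given. A replicate with more reads, or with more control reads, yields more and weaker peaks at the same threshold, so differences in peak number between the lists are not measurements of H3K36me3.

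Peaks were joined to the GENCODE M21 annotation of the same assembly, after chromosome lengths were checked against the peak coordinates. Coordinates are 1-based on mm10. The tested genes were 21728 protein-coding genes on chromosomes 1 to 19 and X, one per symbol. For each gene and replicate, the share of bases from the gene's start to its end that lay in peaks was computed. A gene was called marked when at least 20% of its body lay in peaks in replicate 1 and in replicate 2. Genes that overlap another protein-coding gene share its peaks, because a peak has no strand. Of the tested genes, 4714 overlap another one. Among the genes named below these include Ubr4, Ppox, Rpl13, Supt6, Zfp646, Stab1, Plscr3, Selenoo, Coro1b, Dcaf11, Glul and Nnat.

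Peak lists were compared at an overlap of at least 1 bp. The overlap counts were checked against bedtools 2.31.1. Chance levels came from 100 circular shifts of the peaks along each chromosome, which allow a smallest permutation p of 0.0099. Genome classes were assigned in the order promoter (1 kb on either side of a transcription start), exon, intron and intergenic, from protein-coding genes alone. Pearson and Spearman correlations across genes were tested with 100000 permutations. Gene lists were tested with two-sided Fisher's exact tests against all other tested genes, adjusted by the Benjamini-Hochberg method over 22 lists. Coverage along the gene and in exons against introns was compared in marked genes of at least 10 kb with exact binomial tests across genes, with Wilson 95% intervals. In these tests genes are the units and not replicates, so a p-value describes these 2 libraries and not a population of livers. Values of the 2 replicates are given as mean ± SD, and values from the pooled and replicated lists have no SD. With 1 group of 2 samples, no test between groups of samples was possible. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

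The steps were tested on simulated peaks placed on the real genes. All of 200 genes simulated with 35% of the body covered were called marked (100%), and 0% of 200 genes simulated with 5% covered. Among 1000 random lists of 30 genes, 4.7% gave a Fisher exact p under 0.05.

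The groups, the gene lists, the tests and most alternatives were fixed before the data were examined. The named genes follow a rule fixed at the same time. It takes from each list of symbols the 2 members with the highest and the 2 with the lowest mean coverage (ties by symbol), from each family defined by its symbol pattern the 2 highest, and Alb, Afp, Hnf4a, Gata1, Klf1, Tfrc, Setd2, Hba-a1, Cdh5 and Ptprc. It adds the 10 genes with the most bases in replicated peaks, the 5 longest domains (replicated peaks merged over gaps of up to 3 kb), the 5 replicated peaks with the highest signal value, the 5 genes of at least 5 kb with the largest difference between the replicates in each direction, and 8 long non-coding RNA genes. Genes named outside the rule are identified as chosen after their values were seen. The alternatives were stricter peak thresholds (−log10 p of at least 5, −log10 q of at least 2), other overlaps, other coverage limits, gene length filters, genes that overlap no other gene, the pooled or replicated list in place of the replicates, each replicate alone, and random lists matched on gene length (10000 for each list). A further set was chosen after seeing the data. Its 3 settings counted any peak base as a mark, counted repeat-free bases only, or left out the pseudoautosomal genes of the X. For the hepatoblast, erythroid and globin lists, any peak base was also compared with random lists matched on gene length. Peaks on chromosome Y and on unplaced scaffolds were left out of the gene comparisons. The signal tracks that the deposited notes list were not used here.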

Results

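The series measured H3K36me3 by ChIP-seq in the liver of B6NCrl mouse embryos at embryonic day 11.5. The fetal liver of this age holds hepatoblasts, the precursors of hepatocytes and bile duct cells, together with blood-forming cells that settle there. H3K36me3 is laid down along gene bodies during transcription by the methyltransferase Setd2. There was 1 group of 2 biological replicates, each a pool of embryos of both sexes, and no other mark, age or tissue. The comparisons are therefore between the replicates, between parts of the genome and between groups of genes. Replicate 1 had 124268 peaks covering 42.2 Mb, and replicate 2 had 106567 peaks covering 38.9 Mb. Their mean was 1.54% ± 0.0866 (SD, n = 2) of chromosomes 1 to 19 and X. The median peak width was 263 bp in replicate 1 and 278 bp in replicate 2. The deposited list from the pooled reads had 110089 peaks and the list of replicated peaks had 87682.

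H3K36me3 peaks lay almost entirely in protein-coding genes or next to their starts. Of the peak bases, 94.96% ± 0.882 (SD, n = 2) fell in promoters, exons or introns, which make up 40.0% of chromosomes 1 to 19 and X. Exons held 26.6% ± 1.02 of the peak bases against 3.27% of the genome, an 8.14-fold excess. Introns held 67.8% ± 0.00845 against 35.2% of the genome. Intergenic sequence held 5.04% ± 0.882 against 59.95%. The 1 kb on either side of transcription starts held 0.554% ± 0.149 of the peak bases and 1.56% of the genome, so promoters were depleted. Among 100 circular shifts of the peaks, the share inside genes was 41.5% on average and at most 44.1%, and the one-sided permutation p was 0.0099, the smallest that 100 shifts can give. The promoter share of the shifted peaks ranged from 1.49% to 1.89%, above the observed share in every shift (two-sided permutation p = 0.0099).

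In each replicate, a larger share of the strongest peaks than of the weakest overlapped a peak of the other replicate. Of the replicate 1 peaks, 51.9% overlapped a replicate 2 peak, and 59.3% of the replicate 2 peaks overlapped a replicate 1 peak. When at least 50% of the peak had to be covered these shares were 39.7% and 44.5%, and with a reciprocal overlap of at least 50% they were 25.5% and 29.7%. The bases shared were 30.1% of the bases in either list. After circular shifts the shares at 1 bp and the shared bases averaged 2.88%, 3.33% and 0.881%, and no shift reached the observed ones (one-sided permutation p = 0.0099, the smallest possible). The shifts also move peaks off the genes in which most of them lie. This chance level therefore does not show how much overlap would arise from peaks placed anywhere within the same genes. Among the replicate 1 peaks in the highest 20% by signal value, 77.97% were shared, against 38.3% in the lowest 20%. The corresponding shares of replicate 2 peaks were 82.9% and 44.5%. Shared peaks of replicate 1 had a median width of 327 bp and unshared ones of 226 bp. The highest 20% by signal value were also wider than the lowest 20% (median 422 bp against 220 bp in replicate 1), which eases an overlap of 1 bp. With both lists cut to −log10 p of at least 5, 38.6% of replicate 1 and 56.6% of replicate 2 peaks were shared. At −log10 q of at least 2 these shares were 35.2% and 63.8%, so the replicate 1 share fell under both cuts. The first cut left 57496 peaks in replicate 1 and 37179 in replicate 2, and the second left 76626 and 38950. Far fewer replicate 2 peaks than replicate 1 peaks were then left to overlap. The fall therefore does not show that stronger replicate 1 peaks are shared less.

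The pooled and replicated lists were set against the single replicates to see how far each rests on either library. A peak of replicate 1 overlapped 80.4% of the replicated peaks and a peak of replicate 2 overlapped 78.3%, a mean of 79.4% ± 1.51 (SD, n = 2). Both replicates had a peak at 54710 of the replicated peaks (62.4%), and neither had one at 3222. A peak of replicate 1 overlapped 73.0% of the pooled peaks and a peak of replicate 2 overlapped 70.5%, a mean of 71.8% ± 1.72 (SD, n = 2), and neither had a peak at 7656 of the 110089. The 22407 pooled peaks left out of the replicated list had a median −log10 p of 3.53, against 5.31 for those in it.

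Across genes, the share of the gene body covered by peaks was close in the 2 replicates. Pearson's r across 21728 protein-coding genes was 0.944 and Spearman's rho was 0.907 (both two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates, and 10007 of them had no peak in either replicate, so these values describe the 2 libraries. The 5 genes of at least 5 kb with the largest excess in replicate 1 were Slc37a4, the glucose-6-phosphate transporter, with 43.0% of the body covered in replicate 1 and 7.42% in replicate 2, and Plscr3, Psmc5, Amt and Paf1. The largest excess in replicate 2 was at Qtrt1, which was covered by 11.99% in replicate 1 and 39.6% in replicate 2, followed by Selenoo, Coro1b, Dcaf11 and Vhl. Vhl, the ubiquitin ligase subunit that controls the hypoxia response, was covered by 2.94% and 26.8%. Among genes that reached 20% in either replicate, the median absolute difference between the replicates was 4.84 percentage points.

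**Figure D1:**
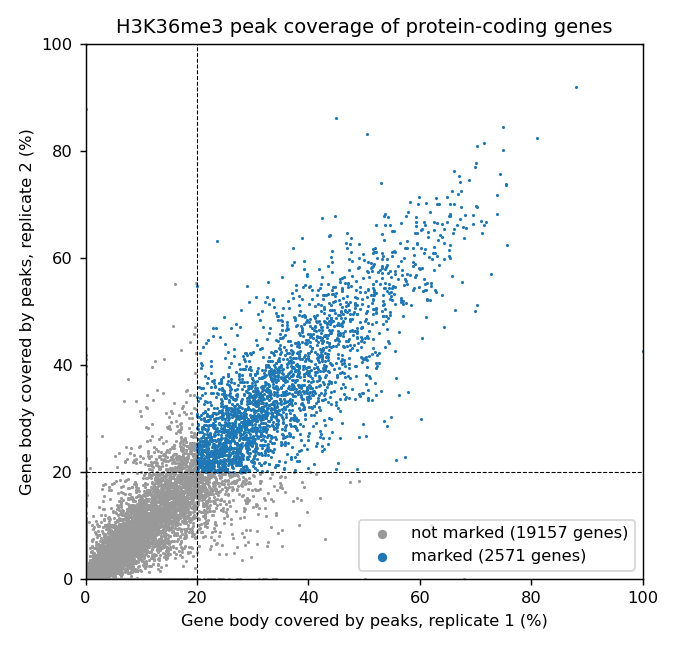
Share of the gene body covered by H3K36me3 peaks (%) in replicate 1 (x axis) and replicate 2 (y axis), with 1 point for each of 21728 protein-coding genes. Dashed lines stand at 20%, and the 2571 genes above both lines are the marked genes (blue); Pearson's r across genes was 0.944.

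At least 20% of the gene body was covered in both replicates for 2571 of the 21728 genes (11.8%). The limit was reached in replicate 1 by 3025 genes and in replicate 2 by 2953, and each count includes these 2571. Of the 10 genes with the most bases in replicated peaks, the first was Gm20388 (4435 kb, with 332983 bases in replicated peaks), and it and Fgfr2 (2961 kb) are gene models that span other genes. Their coverage was 6.62% ± 0.413 and 1.95% ± 0.185 (SD, n = 2), and their peaks are not assigned to either model with certainty. The next after Gm20388 was the ubiquitin ligase gene Ubr4 (chromosome 4, 139352609 to 139489588, with 91298 bases), with 52.7% ± 0.943 (SD, n = 2) of its 137 kb covered. Trrap, a scaffold of histone acetyltransferase complexes, had 53.2% ± 0.147 covered. The chromatin remodellers Chd2 and Smarca4 had 43.7% ± 2.24 and 45.1% ± 0.252 covered. The transcription factor gene Gtf2i had 58.6% ± 1.94, the ubiquitin ligase genes Nedd4 and Hectd4 had 48.4% ± 2.65 and 33.2% ± 0.807, and Cit, a kinase needed for cytokinesis, had 29.3% ± 1.54. The count of marked genes depends on the limit and on gene length. It was 4611 at 10% and 245 at 50%, and among genes of at least 100 kb only 17 of 2487 were marked.

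Gene lists were used to ask which functions and cell types the marked genes belong to. Among the 22 lists, 6 had more marked members than the other genes and 4 had fewer (Fisher's exact test, adjusted p under 0.05). The highest share was in DNA replication and cell division, with 28 of 33 members marked (84.8% against 11.7% of other genes, two-sided Fisher's exact adjusted p = 9.33e-21). Ncapd2, a condensin subunit, was covered over 75.6% ± 7.62 (SD, n = 2) of its body and Mcm2, part of the replicative helicase, over 68.2% ± 4.63. The lowest members were Pola1, which is on the X and 327 kb long, at 0.723% ± 0.218 and Dhfr at 13.6% ± 3.91. In the splicing list 22 of 29 were marked (75.9%, exact adjusted p = 1.12e-14), led by Prpf8 at 68.4% ± 1.64 and Snrnp70 at 65.2% ± 1.74, 2 spliceosome components. Srsf10 (10.6% ± 8.54) and Srsf1 (20.0% ± 0.543) were lowest. Of the ribosomal protein genes, 61 of 83 were marked (73.5%, exact adjusted p = 8.09e-38), with Rpl13 at 74.5% ± 1.29 and Rps19 at 73.8% ± 5.44.

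Haem synthesis was the blood-related list with most marked members. Of 12 genes, 9 were marked (75% against 11.8% of other genes, two-sided Fisher's exact adjusted p = 2.22e-06). Alad, which makes porphobilinogen, was covered over 46.4% ± 4.28 (SD, n = 2) and Ppox, which makes protoporphyrin, over 43.3% ± 2.84. Alas2, the erythroid enzyme of the first step, is on the X and was covered over 2.52% ± 1.76. Cpox had 11.3% ± 0.895. No member of this list had 50% of its body covered in both replicates. Of the 30 erythroid genes, 5 were marked (16.7%), which did not differ from other genes (exact adjusted p = 0.432). Counting any peak base in both replicates, an alternative chosen after seeing the data, 26 of 30 had one against 43.2% of other genes (86.7%, exact adjusted p = 4.13e-06), and random lists with the same gene lengths had 15.4 on average (two-sided permutation p = 0.0002). At 10% of the gene body it was 36.7% against 21.2% (exact adjusted p = 0.0553). The transferrin receptor gene Tfrc (chromosome 16, 32608920 to 32632794) had 40.3% ± 1.16 and the erythropoietin receptor gene Epor had 37.3% ± 14.7, with replicates at 27.0% and 47.7%. The other 3 marked members, named after their values were seen, were Ldb1, Zfpm1 and Ermap. The erythroid transcription factor gene Klf1 had no peak in replicate 1, 18.3% in replicate 2 and 24.4% in both the pooled and the replicated list, and Gata1, on the X, had 1.09% ± 1.54. Trim58 had 0.787% ± 1.11. None of the 10 globin genes had a peak in either replicate, including Hba-a1 (955 bp) and Hba-a2 (exact adjusted p = 0.648 for the share marked). Counting any peak base, chosen after seeing the data, the globin list fell below other genes (0 of 10 against 43.3%, exact adjusted p = 0.0092), but these genes are short (median 1433 bp), and random lists with their lengths, also tried after seeing the data, had 0.727 members with any peak on average (two-sided permutation p = 0.93). The α-globin copies are near-identical, and where the aligner placed their reads is not given.

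None of the 33 hepatoblast genes was marked. Against 11.9% of other genes this gave an unadjusted exact p of 0.0279 and an adjusted p of 0.0557, short of the threshold. The albumin gene Alb (chromosome 5, 90460897 to 90476602) had 5.53% of its body covered in replicate 1 and none in replicate 2. Afp, the fetal serum protein gene next to it, and Ahsg had no peak. Hnf4a, a main transcription factor of hepatocytes, had 0.345% ± 0.488. The highest members were Apoe at 20.8% ± 3.70 (SD, n = 2), with replicates at 23.4% and 18.2%, and Krt18 at 11.9% ± 5.605. Apoe had 36.5% in the pooled and 26.3% in the replicated list, and was the 1 hepatoblast gene that passed 20% in either of these lists or in replicate 1 alone. Against random lists matched on gene length the hepatoblast list was below chance (two-sided random-list permutation p = 0.015, adjusted 0.038), and over the alternatives run its adjusted p ran from 0.0136 to 1. The list passed the threshold with replicate 2 alone, with pooled peaks and at 10% of the gene body (Fisher's exact adjusted p = 0.0361, 0.0471 and 0.0136), and with any peak base and with repeat-free bases, both chosen after seeing the data (exact adjusted p = 0.0389 and 0.0348). Of 25 genes of mature hepatocytes 1 was marked, the glutamine synthetase gene Glul at 42.1% ± 2.39 (exact adjusted p = 0.409). Glul overlaps another protein-coding gene and shares its peaks there, and none of the 23 list members that overlap no other gene was marked. Slc10a1, a bile acid transporter, had 16.1% ± 2.52, and Abcb11 and Aldob had no peak.

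Lists of other cell types, including those of neighbouring organs, neurons and muscle, had no marked member. These were progenitor, myeloid and megakaryocyte genes (20 genes), lymphoid genes (20), endothelial genes (20), mesenchymal and mesothelial genes (22), genes of neighbouring foregut organs (18), neuronal genes (25) and muscle genes (27). None of these 7 lists passed the threshold, with Fisher's exact adjusted p between 0.114 and 0.317. Under some alternatives they did pass, below other genes. With pooled peaks these were all but the foregut list (exact adjusted p from 0.0189 to 0.0471), at 10% of the gene body all but the endothelial list (0.00655 to 0.02595, exact), and with replicated peaks the neuronal and muscle lists (exact adjusted p = 0.0452 and 0.03175). With any peak base, chosen after seeing the data, they were all but the progenitor and mesenchymal lists. In the progenitor list Myb had 5.57% ± 3.73 (SD, n = 2) and Kit 5.29% ± 0.156 covered, and Cd34, Cd48 and Ptprc had no peak. Stab1, a scavenger receptor of sinusoidal endothelium, had 14.0% ± 0.704, Eng 4.06% ± 0.800 and Cdh5 0.216% ± 0.305, while Cldn5 and Lyve1 had none. The mesenchymal genes Vim and Pdgfrb had 12.2% ± 3.62 and 5.31% ± 1.19, and Acta2 and Dcn had none. The highest lymphoid genes were Bcl11b (0.849% ± 0.289) and Lck (0.723% ± 1.02), and Blk and Cd19 had no peak. Sftpb (2.70% ± 3.82), Slc17a7 (0.791% ± 1.12), Elavl3 (0.4997% ± 0.707), Mybpc3 (1.96% ± 2.78) and Myh7 (1.36% ± 1.92) led the foregut, neuronal and muscle lists, each with a peak in replicate 1 only. Barx1, Cdx1, Ascl1, Dlx1, Acta1 and Ckm had no peak.

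Gene families differed in the share marked. Of 365 Zfp zinc finger genes, 87 were marked (23.8% against 11.6% of other genes, two-sided Fisher's exact adjusted p = 4.77e-10), led by Zfp869 (76.5% ± 7.11, SD, n = 2) and Zfp646 (74.6% ± 1.14). None of 1092 olfactory receptor genes was marked (exact adjusted p = 1.68e-60), none of 326 vomeronasal receptor genes (exact adjusted p = 8.95e-18), none of 67 replication-dependent histone genes (exact adjusted p = 0.00113) and none of 39 Hox genes (exact adjusted p = 0.0259). The members with most coverage in these families were Olfr533 (1.94% ± 2.75), Olfr552 (0.893% ± 1.26), Vmn1r199 (1.12% ± 1.58), Vmn1r80 (0.659% ± 0.933), Hist1h1d (1.25% ± 1.76), Hist1h2be (0.306% ± 0.432), Hoxb2 (4.21% ± 5.96) and Hoxa5 (3.85% ± 5.44). Histone genes are short, with a median of 539 bp, and against random lists matched on length they did not pass the threshold (random-list permutation adjusted p = 0.16). The calls of the histone and Hox lists were also lost with peaks of −log10 p of at least 5 (Fisher's exact adjusted p = 0.141 and 0.543; over the alternatives run, both ran up to 1). At 50% of the gene body the vomeronasal call was lost as well (exact adjusted p = 0.206).

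Of 21 genes for enzymes and readers of H3K36 methylation, 7 were marked (33.3% against 11.8% of other genes, two-sided Fisher's exact adjusted p = 0.0203). Kdm4a, a demethylase, had 45.8% ± 0.520 (SD, n = 2) and Supt6, an elongation factor that recruits Setd2, had 44.2% ± 1.28. Setd2 itself (chromosome 9, 110532597 to 110618633) had 21.04% ± 0.858. Kdm4c (1.86% ± 1.31) and Phf19 (1.99% ± 1.48) were lowest. The excess of this list did not pass the threshold with peaks of −log10 p of at least 5 (9.52% marked, exact adjusted p = 0.573) or among genes that overlap no other (23.1%, exact adjusted p = 0.265), and over the alternatives its adjusted p ran from 5.59e-08 to 1. Of 20 imprinted genes 2 were marked (exact adjusted p = 1), Nnat at 36.9% ± 4.05 and Igf2r at 25.03% ± 3.47. Nnat overlaps another protein-coding gene and shares its peaks. Cdkn1c and Ndn had no peak.

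**Figure D2:**
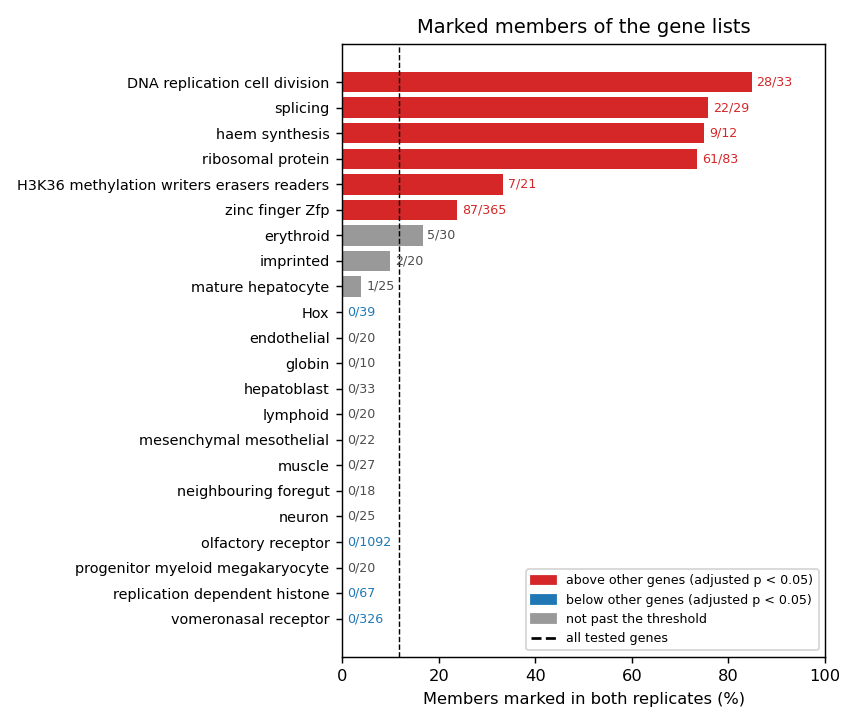
Share of the members of each gene list that were marked in both replicates (%), with the number marked and the number tested beside each bar. The dashed line is the share among all tested genes (11.8%); red bars and numbers are lists above and blue numbers lists below the other genes at an adjusted p under 0.05, and grey lists did not pass.

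Within marked genes, peaks covered a larger share of the 3′ part than of the 5′ part, and a larger share of exon bases than of intron bases. Of 1790 marked genes of at least 10 kb, 1584 (88.5%, Wilson 95% interval 86.9% to 89.9%) were covered more in the last of 3 equal parts than in the first of them (two-sided exact binomial p = 3.36e-263). The median coverage was 18.7% in the first part and 42.8% in the last. In 10 equal parts of the gene, the mean coverage was 5.05% ± 0.530 (SD, n = 2) in the part next to the transcription start, 46.7% ± 1.15 in part 9 and 40.5% ± 0.577 in the last. Within 1 kb of the transcription start it was 0.869% ± 0.348, and within 1 kb of the gene end 30.8% ± 0.156. In 1341 of 1780 such genes with at least 2 introns (75.3%, Wilson 95% interval 73.3% to 77.3%), a larger share of exon bases than of intron bases lay in peaks (two-sided exact binomial p = 6.37e-106). The medians were 42.1% of exon bases and 30.0% of intron bases. In the 3′ 50% of the gene alone the share of genes was 64.8% (exact binomial p = 6.62e-36).

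**Figure D3:**
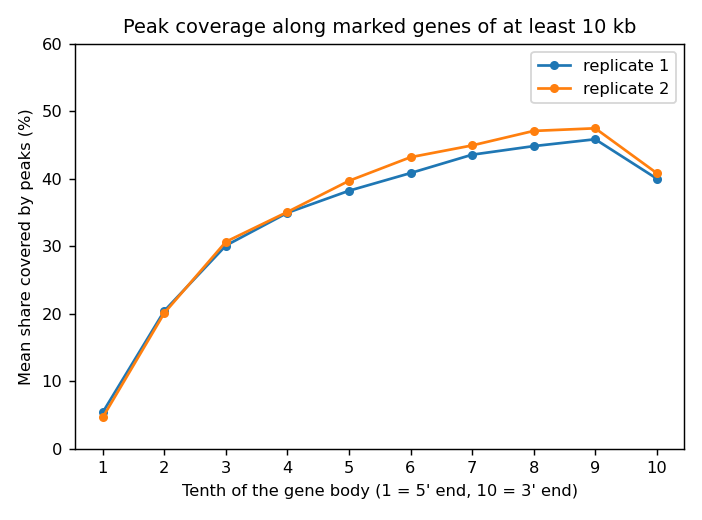
Mean share of bases covered by H3K36me3 peaks (%) in each of 10 equal parts of the gene body, from the 5′ end (1) to the 3′ end (10), over 1790 marked genes of at least 10 kb, with 1 line for each replicate. The mean of the replicates was 5.05% in part 1, 46.7% in part 9 and 40.5% in part 10.

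The X chromosome carried few marked genes. Of 948 X-linked protein-coding genes 6 were marked (0.633%), against 2565 of 20780 autosomal genes (12.3%; two-sided Fisher's exact p = 1.2e-43, odds ratio 0.0452). The X share was 1.69% without replicate 1 and 0.738% without replicate 2 (14.1% and 14.5% of autosomal genes), and 2.43% against 22.1% at 10% of the gene body. Counting any peak base in both replicates, an alternative chosen after seeing the data, it was 16.2% against 44.5%. The direction was the same but the gap was smaller, so its size depends on the coverage limit. The share on single autosomes ran from 7.76% on chromosome 14 to 16.6% on chromosome 5. Peaks covered 0.151% of the X in replicate 1 and 0.158% in replicate 2, and the least covered autosome had 1.02% and 0.923%. The 6 genes, named after their values were seen, were Hcfc1 (42.3% ± 9.94, SD, n = 2), a transcriptional co-regulator, Asmt (27.7% ± 1.82), Gm21887 (27.5% ± 3.12), the RNA-binding protein gene Rbm3 (25.6% ± 3.16), the histone demethylase gene Kdm5c (25.3% ± 0.102) and the translation factor gene Eif2s3x (23.04% ± 2.80). Asmt and Gm21887 lie in the pseudoautosomal region, which the X shares with the Y.

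**Figure D4:**
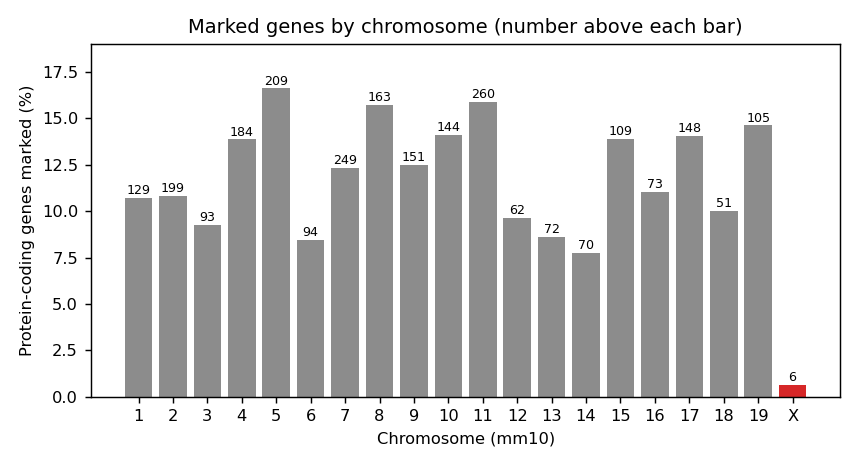
Share of protein-coding genes marked in both replicates (%) on each chromosome of mm10, with the number of marked genes above each bar. The X (red) had 0.633%, and the autosomes lay between 7.76% and 16.6%.

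Replicated peaks merged over gaps of up to 3 kb gave 19101 domains with a median length of 1742 bp, of which 931 were longer than 20000 bp. The longest spanned 102 kb at Ubr4 (chromosome 4, 139389852 to 139492011), of which 17.2% was exon, 80.4% intron and 2.37% intergenic. Of this length 77.5% lay in replicated peaks and the rest in the gaps between them. The others were 90.9 kb at Trrap (chromosome 5, 144770683 to 144861561), 89.1 kb at Chd2 (chromosome 7, 73433688 to 73522828), 85.7 kb at Nedd4 (chromosome 9, 72663782 to 72749438) and 84.6 kb at Hectd4 and Trafd1 (chromosome 5, 121290803 to 121375409). Of their lengths 68.5%, 60.4%, 57.4% and 58.7% lay in replicated peaks, in that order. With gaps of up to 1 kb the longest was 49.2 kb, also at Ubr4, and with gaps of up to 10 kb it was 159.8 kb at Herc1, Usp3 and Fbxl22. All 5 replicated peaks with the highest signal value lay at zinc finger genes. The highest, with a signal value of 14.8, covered chromosome 7, 5027919 to 5034076, at Zfp865, Ccdc106 and Gm44973, and 82.6% of it was exon. The others were at Zfp146 (chromosome 7, 30160667 to 30164359, signal 13.4), Zfp329 (chromosome 7, 12809210 to 12811701, 12.9), Zfp763 (chromosome 17, 33017696 to 33020323, 12.7) and Zfp35 (chromosome 18, 24002352 to 24005209, 12.1), of which 54.3%, 98.6%, 86.5% and 89.6% were exon.

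Among 8 long non-coding RNA genes, Malat1, a nuclear RNA (chromosome 19, 5795690 to 5802672), had the most coverage, with 38.2% ± 3.59 (SD, n = 2). Airn, the antisense transcript of the imprinted Igf2r locus, had 10.5% ± 3.45, and it overlaps Igf2r. Coverage was 4.59% ± 2.87 at Meg3, 3.46% ± 4.89 at H19 with a peak in replicate 2 only, 3.31% ± 0.722 at Kcnq1ot1 and 1.17% ± 0.0715 at Neat1. Xist, the RNA that silences an X chromosome in female cells, had 1.33% ± 0.562 and its antisense gene Tsix 0.569% ± 0.241. Xist lies wholly within the span of Tsix, so the 2 values share peaks and are not separate measurements. The replicated list had no peak at either gene.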

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

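Peaks outside the chromosomes used for the gene comparisons were counted because they are signal in data that no comparison used. The depth is unknown and there is no control list, so the counts describe the lists and were not tested. Replicate 1 had 9 peaks on chromosome Y and 37 on unplaced or unlocalised scaffolds. Replicate 2 had 8 on chromosome Y and 11 on scaffolds. The pools held embryos of both sexes. On the Y, 1 peak of replicate 1 lay in Kdm5d (941315 to 941655) and 2 peaks of replicate 2 lay in Ddx3y (1278533 to 1278865 and 1279162 to 1279341), the Y-linked partners of Kdm5c and Ddx3x. The remaining Y peaks of both replicates lay between 90723622 and 90745855, in no gene of the annotation used here.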

How the results depend on the processing

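Direction and side of the threshold were kept under all alternatives run for the overlap of the replicates, the correlation across genes, the genome classes, the position along the gene, exons against introns and the X. The alternatives of any peak base, repeat-free bases and no pseudoautosomal genes were chosen after seeing the data. Leaving out a replicate gave 2953 or 3025 marked genes. Coverage of the named genes moved by more than the replicate SD for 52 genes with −log10 p of at least 5 and for 41 with pooled peaks. The depth is unknown, so weak coverage is not evidence of absence.

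The share of replicated peaks overlapped by a single replicate (mean of the 2) moved from 79.4% to 71.6% at an overlap of 50% of the peak, to 63.5% with −log10 p of at least 5 and to 61.5% with −log10 q of at least 2. For pooled peaks it was 64.8%, 62.3% and 59.1%. The count of marked genes was 1168 with −log10 p of at least 5, 1311 with −log10 q of at least 2, 4611 at 10% of the gene body, 245 at 50% and 9407 for any peak base. Fewer or more bases then reach the limit by construction.

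Of the lists, 10 passed the threshold as reported, 4 of them below other genes. The count was 17 at 10% (11 below), 5 at 50% (1 below), 17 with pooled peaks (11 below) and 20 for any peak base (12 below). The lists below were 2 with −log10 p of at least 5, 2 with −log10 q of at least 2 and 2 for genes of at least 5 kb. At 50%, where 1.13% of other genes were marked, the erythroid, haem synthesis and H3K36 methylation lists had 0% marked (Fisher's exact adjusted p = 1 in each), so lists of this size show no change of direction there. Direction against other genes changed for imprinted genes at 10% (25%, exact adjusted p = 0.595) and with any peak base (70%, exact adjusted p = 0.0269), and with any peak base for mesenchymal genes (45.5%, exact adjusted p = 0.833). The causes were not tested. Besides these rows, 28 calls of lists were gained and 14 lost over all alternatives. Hepatoblast genes passed the threshold, below other genes, without replicate 1 (Fisher's exact adjusted p = 0.0361). Without replicate 2 their share was also lower, with 1 of 33 marked (3.03% against 13.9%), but short of the threshold (exact adjusted p = 0.122).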

Other observations

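A larger share of the strongest peaks than of the other peaks lay in Zfp zinc finger genes. Of the 100 replicated peaks with the highest signal value, 34 lay in a Zfp gene, against 1732 of the other 87567 (1.98%; two-sided Fisher's exact p = 2.59e-32). This test was chosen after the 5 highest peaks, all at zinc finger genes, were seen. Without these 5, 29 of the remaining 95 lay in a Zfp gene (30.5%, two-sided Fisher's exact p = 2.92e-26) and 66 lay elsewhere.

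Of 19091 domains on chromosomes 1 to 19 and X, 386 (2.02%) touched no annotated gene of any type, and 4 of these were longer than 5 kb. The longest, on chromosome 4 (11175625 to 11184981, 9.36 kb), starts 1245 bp past the 3′ end of Trp53inp1, a p53 target gene on the plus strand, and 60.4% and 57.4% of it lay in peaks of replicates 1 and 2. The next lay on chromosome 17 (36273454 to 36281923), 1206 bp upstream of the 5′ end of Trim39, with 28.7% and 29.3% in peaks of the replicates. Another lay on chromosome 14 (66973106 to 66981481), 2521 bp past the 3′ end of the small RNA gene Gm24258, with 13.7% and 16.5%. The remaining one over 5 kb was on chromosome 3 (27084420 to 27089843), 7378 bp from the 3′ end of Ect2, with 24.7% and 26.4%. The rest of each length lay outside the peaks of that replicate.

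For the patterns that follow, the tests of escape genes, of any peak, of the other small cell populations and of p at equal signal were chosen only after the result was seen. No difference between groups of samples exists in this design, so no biological explanation was tested across conditions.

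Few X-linked genes were marked. For lower depth on the X alone, the prediction fixed beforehand was a median signal value of X peaks at or above the autosomal median. Instead it was lower in both replicates (3.17 against 3.38 in replicate 1, 3.32 against 3.55 in replicate 2, mean difference −0.216). These values argue against lower depth only if this score does not fall with depth. How it responds to depth is not given, so lower depth stays open. If reads in repeats had been lost, X-linked genes would recover over repeat-free bases, but the X share there was 0.0619 of the autosomal share. A lack of ubiquitously expressed genes on the X is argued against as the only reason. None of the 5 X-linked members of the ribosomal protein, splicing and DNA replication lists was marked, against 111 of 140 autosomal ones (two-sided Fisher's exact p = 0.000559). These 5 were Pola1 and the ribosomal protein genes Rpl10, Rpl36a, Rpl39 and Rps4x, with no splicing gene. Rpl39, Rps4x and Pola1 held peaks in both replicates, below the limit. Whether such a lack contributes was not tested. Of these 5, Pola1 is 327 kb long, and among genes of at least 100 kb only 17 of 2487 were marked. The single active X per cell stays open too, because the 8 genes known to escape X inactivation were covered 9.13 percentage points more than other X-linked genes (mean 10.1%, median 6.505%, against a mean of 0.944%; one-sided permutation p = 9e-05), but 2 of them, Kdm5c and Eif2s3x, had been seen among the marked genes when the test was chosen. Without these 2 the difference was 4.42 percentage points (one-sided permutation p = 0.014) and the median 1.78%, several of the genes are broadly expressed, and this does not decide.

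No hepatoblast gene was marked, although the adjusted test fell short. Gene length is argued against, since random lists of the same lengths had 4.41 marked members on average (two-sided permutation p of the random lists = 0.015). A limit of 20% that is too strict for these genes stays open, because 8 of 33 had any peak in both replicates, against 26 of 30 erythroid genes (two-sided Fisher's exact p = 7.18e-07), but the erythroid genes are longer (median 23884 bp against 10255 bp), and random lists with the lengths of the hepatoblast genes had 13.2 with any peak (two-sided permutation p = 0.078). A small share of hepatoblasts among the cells stays open too, because cell shares and transcription were not measured. The endothelial, mesenchymal and progenitor lists had 0 of 62 marked against 5 of 30 erythroid genes (two-sided Fisher's exact p = 0.0029), but these counts were known when the comparison was chosen, and 10 of 22 mesenchymal genes (45.5%) had a peak in both replicates, so it decides nothing.

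Replicate 1 had more peaks than replicate 2. For GC content, the difference in gene coverage between the replicates had a Spearman rho of 0.0771 with gene GC content across genes. Among genes that reached the coverage limit in either replicate, rho was 0.0675. The mean difference there (replicate 1 minus replicate 2) was −0.261 percentage points, so these genes did not show the excess of replicate 1. Over all genes, mean coverage was higher in replicate 1 on every autosome but chromosome 15, for example 9.39% against 8.74% on chromosome 11, and lower on the X. Unshared peaks had a median GC content of 47.2% in replicate 1 and 47.0% in replicate 2. These values show no strong link with GC content. However, 10007 of the 21728 genes had no peak in either replicate, so their differences were tied, and the spread of peak GC content is not given. GC content therefore stays open. At signal values of 4.0 to 4.2, the median −log10 p of replicate 1 peaks was 1.16 higher (6.45 against 5.29), but the scaling of the signal value is not given, so equal values in the 2 lists need not be equal enrichment. Whether replicate 1 had more reads, or more control reads, stays open, and replicate 1 was called against 2 control alignments and replicate 2 against 1.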
